A study of Trachinotus carolinus with 20 samples.

How the data were processed

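Liver RNA of Florida pompano (Trachinotus carolinus), a marine food fish, was measured by RNA sequencing in 20 tanks, 4 on each of 5 diets. Per the labels' protocols, total RNA came from 2 fish of each tank and was sequenced on an Illumina HiSeq. Whether the livers of a tank were pooled is not given in the sources used here, so each tank was taken as 1 replicate. The diet of each tank came from its treatment label, and replicates were numbered within a diet in sample order, which pairs no tanks across diets.

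The authors deposited a table of normalized signal per gene and a matching table per isoform of a de novo transcriptome with Trinity-style names. The gene table holds 226105 Trinity genes. Its values were read as TPM rescaled between tanks by TMM factors, because each tank summed to between 909166 and 1086881 and the table is named for TMM expression. Trim Galore 0.6.7, Salmon 0.13.1, DESeq2 1.38.0 and R 4.2.0 are named, without role or order, per the submitters' processing notes. The assembler's version, the library kit and the strand setting are not given in the sources used here. TPM keeps no read depth, so the depth of each tank is unknown, and no counting interval or detection floor is given. TPM is relative, so a gene can also fall because others took a larger share.

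Gene names came from the deposited Trinotate table, as the best Swiss-Prot hit of a vertebrate protein. A hit was found for 75059 Trinity genes, and for 74250 of them the best hit was a vertebrate protein. Such names rest on protein similarity, and 1 pompano gene can be split over several Trinity genes, so a level belongs to the Trinity gene and not to the whole gene. Identity to the hit was 77.6% for MIOX, 79.6% for SLC25A12 and 81.8% for GPDM. It was only 25.9% for BT2A2, 31.4% for APOEB, 37% for G0S2 and 38.1% for OACYL. Names at such low identity, and the roles given with them, are tentative. At the other extreme, 28389 Trinity genes had a mammalian best hit at 99% identity or more. For mouse best hits alone the number was 14119. Of the 28389, 2314 were among the tested genes. Whether these are pompano sequences was not tested, so a vertebrate name does not by itself mark a pompano gene. No genome was used, so no coordinates are given.

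Values were tested as log2(value + 1) with limma 3.58.1 in R 4.3.3, and the package data.table, version 1.17.8, was used for reading. Trinity genes with a value of at least 1 in at least 4 tanks were kept, which left 30844, of which 16916 had a vertebrate name. One mean per diet and 1 spread per gene, shared by the 5 diets, were fitted over all 20 tanks. The moderated statistics were computed with a trend and robustly. The contrasts were starch against flour over both cereals, corn against wheat over both forms, the interaction of cereal and form, dextrinized against native corn starch, a test of any diet difference and the 10 pairs of diets. Tests were two-sided, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05. By chance alone about 5% of the genes tested would have an unadjusted p under 0.05, so such counts by themselves show no difference. Changes are differences of log2(value + 1), which understate the change of low genes, and levels are given as mean ± SD of the normalized TPM.

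The contrasts, the tests, the gene lists, the rule for naming genes and all alternatives other than those named as added were fixed before the data were examined. The rule took, for each of the 4 main contrasts, the 10 largest rises and the 10 largest falls among named genes past the threshold and up to 4 passing members of each list. Where fewer than 10 genes passed, it took the 10 smallest p of the contrast. It also took PKLR, G6PC1, PCK1, FASN, SCD, PYGL, GYS2, SREBF1, CYP7A1 and IGF1 in any case. Results of some genes the rule took are not reported here. SCD had no tested Trinity gene with its name and has no value here. List members given as examples beyond this rule were chosen after their values were seen.

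The 33 gene lists of pathways and of markers of other cell types held 892 symbols, of which 735 were matched to a tested Trinity gene, the one with the highest mean. Lists were tested with camera at a preset correlation of 0.01, adjusted over 132 tests, and again with an estimated correlation and with fry. List levels, the mean over members of log2(value + 1) centred per gene, were compared by exact permutation over 12870 or 70 splits of the tanks. Gene ontology terms were not tested, because no contrast had 20 annotated genes past the threshold.

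The steps were tested on simulated data for 30844 genes with 50 changed at each size. For dextrinized against native corn starch, 32% of changes of 1 on the log2 scale, 70% of changes of 2 and 96% of changes of 3 were recovered. The shares were 52%, 96% and 98% for starch against flour, 62%, 96% and 98% for corn against wheat, and 10%, 50% and 80% for the interaction. Per contrast, 6 to 17 unchanged genes were called too. The simulated genes varied independently, with normal noise and the same SD in every diet, so recovery in the real tanks can be lower. In a simulation of lists of independent genes, the shifted list was recovered by camera with either correlation and by fry, and fry also called 2 unshifted lists. Because the genes were independent, it cannot show how camera at the preset correlation behaves on lists whose members vary together.

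Alternatives covered the pseudocount, the filter, rescaling, the moderation, the tank number as a covariate, the tanks in the fit, the unit of the test, the list member and the list test, and each tank was left out in turn. Others were added after the data were seen: a batch term for tanks 41 to 44, fits without tanks 41 to 44 or without tanks 36 and 43, the pancreas list level as a covariate, removal of genes with a mammalian best hit at 99% identity or more, a filter on tanks above 0, and a contrast of DCS with the other 4 diets. Other splits of the same tanks were counted, all of them for 4 against 4 tanks and 100 drawn otherwise.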

Results

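The study asked how the source of dietary carbohydrate affects Florida pompano. Fish of about 9 g, 400 in all, were spread over 20 tanks of 80 L and fed for 10 weeks on diets holding 14% of 1 carbohydrate source. These were dextrinized corn starch (DCS), a starch partly broken down to shorter chains, native corn starch (CS), starch of wheat (WS), and flour milled from whole corn (CG) or whole wheat (WG). Each diet had 4 tanks, and the liver transcriptome of each tank is given as TMM-normalized TPM. Between 67923 and 83315 Trinity genes were above 0 in tanks 25 to 40, and between 93343 and 100949 in tanks 41 to 44, which hold 1 tank each of WG, CS, WS and DCS and none of CG. The depth is unknown.

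**Figure D1:**
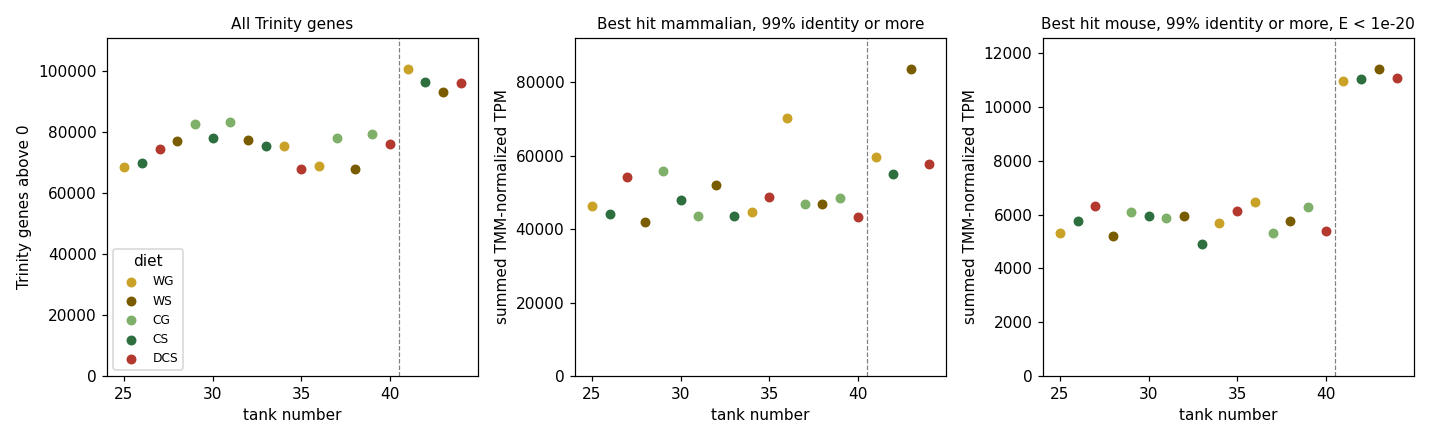
Number of Trinity genes above 0, summed TMM-normalized TPM of genes with a mammalian best hit at 99% identity or more, and the same sum for mouse best hits alone, each against tank number. Points are single tanks, and the dashed line parts tanks 25 to 40 from tanks 41 to 44, whose mouse sums lie at 10972 to 11440 against 4919 to 6488.

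Tanks on the same diet resembled each other little more than tanks on different diets, with a median correlation of 0.912 within and 0.91 between diets.

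The effect of dextrinizing corn starch is the comparison of DCS with CS. G0S2 (TRINITY_DN3172_c0_g1) was named by 37% identity to an inhibitor of triglyceride lipase. Its level rose from 1.29 ± 1.12 in CS to 161 ± 135 in DCS (SD, n = 4), a log2 change of 5.26 (SE 0.86, limma adjusted p = 0.0266). The mitochondrial glycerol 3-phosphate dehydrogenase (GPDM, TRINITY_DN461_c0_g1), part of a shuttle that carries reducing equivalents from the cytosol, rose from 5.66 ± 2.45 to 45 ± 33.1. The mitochondrial aspartate/glutamate carrier SLC25A12 (S2512, TRINITY_DN13252_c0_g1), part of another such shuttle, rose from 2.3 ± 0.708 to 19.8 ± 11.3. Inositol oxygenase (MIOX, TRINITY_DN681_c0_g1), which starts the breakdown of myo-inositol, fell from 384 ± 80.8 to 50.7 ± 29.6, a log2 change of -3.06 (SE 0.36, limma adjusted p = 0.000779).

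The log2 change was 2.52 for both GPDM (SE 0.43, limma adjusted p = 0.0381) and SLC25A12 (SE 0.35, limma adjusted p = 0.00674). The creatine transporter (SC6A8, TRINITY_DN5136_c0_g4) rose by 1.80 (SE 0.29, limma adjusted p = 0.0265), from 0.548 ± 0.206 to 4.64 ± 2.03. In all, 11 Trinity genes passed, 8 higher and 3 lower in DCS, and 6 of them had a vertebrate name. The balance turned to 3 higher and 5 lower with no filter on low values, 1 higher and 3 lower without tanks 41 to 44, and 1 higher and 2 lower without CS replicate 3 or 4, and it was 3 and 3 without CS replicate 2. Of those without a vertebrate name, TRINITY_DN3889_c1_g2 rose by 2.13 and TRINITY_DN13252_c0_g4 by 2.44 on the log2 scale. By its identifier, the latter is in the same Trinity cluster as SLC25A12 (TRINITY_DN13252_c0_g1). It may be a piece of the same gene, which was not tested. TRINITY_DN6678_c0_g3 and TRINITY_DN44988_c0_g1 fell and were listed at 0 in each of the 4 DCS tanks. In CS replicates 1 to 4, the first was at 1.508, 1.365, 3.568 and 1.72, and the second at 1.508, 2.472, 1.777 and 1.684. The second was at 0 in WG, WS and CG as well, so it was seen in the CS tanks alone. Within DCS the tanks differed widely, with G0S2 at 226.8, 310.1, 4.774 and 100.7 in replicates 1 to 4. The SE and p rest on 1 spread shared by the 5 diets. For a gene that varied more within DCS than within the other diets, they can understate the uncertainty. When all Trinity genes named G0S2 were summed, the log2 change was 0.93 and did not pass (limma adjusted p = 0.954). Of the named calls, MIOX was lost only with the DCS and CS tanks fitted alone (limma adjusted p = 0.131) and SLC25A12 in 4 of 36 alternatives, without tanks 41 to 44, CS replicate 3 or CS replicate 4 and with those 2 diets alone (limma adjusted p up to 0.197). The GPDM call was lost in 21 of 36 alternatives (limma adjusted p up to 0.519), among them both rescalings, the batch term for tanks 41 to 44 and every fit without a single tank other than CS replicate 1, DCS replicates 1 and 3, WS replicates 1 and 4 and WG replicates 2 and 3. The G0S2 call was lost in 13 of 36 (up to 0.954), including those without any single CS tank or DCS replicate 1, 2 or 4, and the SC6A8 call in 11 of 35 (up to 0.409), including those without any single CS tank or DCS replicate 2 or 4 and the sum per name (log2 change 1.46, limma adjusted p = 0.0888). Of those without a name, TRINITY_DN13252_c0_g4 was lost in 22 of 35 alternatives (up to 0.46) and TRINITY_DN6678_c0_g3 in 28 of 34 (up to 0.345), the latter without any single tank other than WG replicates 2 and 3, the former other than DCS replicates 1 and 3, WS replicates 1 and 3 and WG replicates 2 and 3. The count of genes was 0 by limma when only the DCS and CS tanks were fitted, with 1766 at an unadjusted p under 0.05, 4 without tanks 41 to 44 and 10 with these tanks as a batch term. It was 6 without CS replicate 2, 3 without CS replicate 3 or 4 and 5 without DCS replicate 4.

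**Figure D2:**
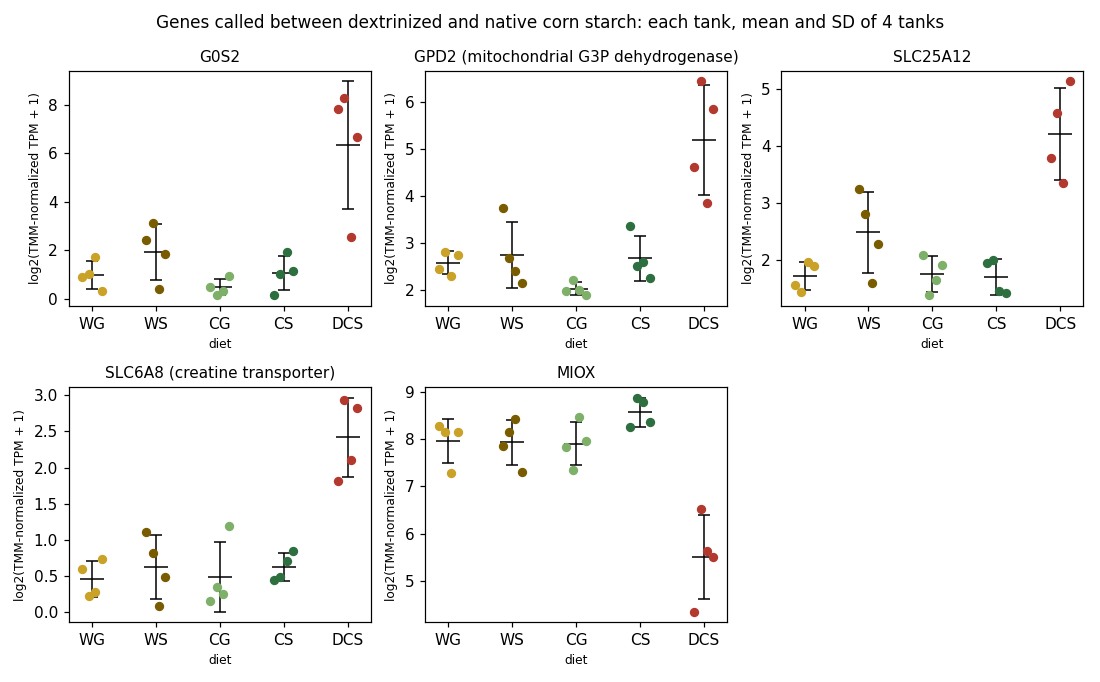
Level of 5 named genes that passed between DCS and CS, on a log2(TMM-normalized TPM + 1) axis, by diet. Points are single tanks, and bars are the mean and SD of 4 tanks. MIOX reached at most 90.77 in the DCS tanks and at least 154.3 in every tank of the other diets.

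Among the fixed lists, 1 member passed over all genes. Adjusted over the list alone, 5 members passed, among them GPAM, BHMT, FABP7 and ZP4. GPAM, the first enzyme of triglyceride synthesis, stood at 11.1 ± 1.67 in DCS and 5.53 ± 0.984 in CS (limma p adjusted over the list alone = 0.012). BHMT, which remethylates homocysteine with betaine, stood at 2880 ± 675 and 6490 ± 1520 (limma p adjusted over the list alone = 0.0079). FABP7, a fatty acid binding protein, with a log2 difference of 2.61, and ZP4, an egg envelope protein, with 0.69, are named here after their values were seen. Of the genes of carbohydrate and lipid metabolism and growth given next, none passed over all genes. Their log2 differences were 0.30 for PKLR, 0.41 for G6PC1, -1.1 for PCK1, 0.51 for FASN, 0.77 for PYGL and -0.34 for GYS2. They were 0.49 for SREBF1, -0.80 for CYP7A1 and -0.26 for IGF1. Without DCS replicate 1 the difference for FASN was -0.05.

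As a group, all 23 measured genes of cholesterol synthesis and uptake were higher in DCS, with a median log2 difference of 0.82 (camera adjusted p = 8.96e-09, and adjusted p = 0.948 with an estimated correlation). None passed alone, and the log2 difference was 1.62 for HMGCS1 and 1.69 for FDPS. Of 27 interferon response genes 25 were higher (camera adjusted p = 0.000412, and adjusted p = 0.948 with an estimated correlation), among them the RNA sensor IFIH1 by 0.62 on the log2 scale. The level of the cholesterol list was 0.854 higher in DCS, which did not pass an exact permutation test (p = 0.143, adjusted p = 0.967), and it ranged from -0.613 to 1.504 over the DCS tanks and from -0.848 to -0.192 over the CS tanks. The interferon list level was higher in 4 of 4 DCS tanks than in any CS tank (exact permutation p = 0.0286, the smallest that 70 splits allow, adjusted p = 0.967). The proteasome (33 of 33 members higher, adjusted p = 0.0124) and oxidative phosphorylation (43 of 48 higher, adjusted p = 0.0237) lists were called higher by camera. Amino acid catabolism (19 of 32 lower, adjusted p = 0.0242) and the methionine and one-carbon list (10 of 18 lower, adjusted p = 0.03) were called lower. With an estimated correlation, the adjusted p was 0.948 for the methionine list and 0.972 for the others of these. No list passed in any of the 4 contrasts with an estimated correlation or with fry. The proteasome call was lost without DCS replicate 1 or CS replicate 3 or 4 (adjusted p up to 0.22), and the oxidative phosphorylation call without DCS replicate 1 or 2 or CS replicate 3 or 4 (up to 0.707). The amino acid call was lost without CS replicate 1 or 2 or DCS replicate 3 or 4 (up to 0.242), and the methionine call without CS replicate 1 or DCS replicate 3 or 4 (up to 0.214). Without tanks 41 to 44 the proteasome (adjusted p = 0.138), oxidative phosphorylation (0.225) and methionine (0.0823) calls were lost, and with every Trinity gene of a name as a member the proteasome (0.347), oxidative phosphorylation (0.767) and amino acid (0.0507) calls were. The exact permutation p of the list level was 0.171 for the proteasome and methionine lists, 0.314 for oxidative phosphorylation and 0.371 for amino acid catabolism.

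Across the diets, 12 Trinity genes differed by limma's test of any diet difference. Those with a vertebrate name included MIOX, SLC25A12, SC6A8, GPDM and G0S2. Of the 12, TRINITY_DN44988_c0_g1, TRINITY_DN52306_c6_g1, TRINITY_DN109037_c0_g1 and TRINITY_DN55774_c0_g1 were above 0 only in the tanks of a single diet. Against the flours, 17 genes passed between DCS and CG, 13 of them higher in DCS, and 15 between DCS and WG, 12 of them higher. Without tanks 41 to 44, which hold no CG tank, the counts were 1 for DCS against CG and 4 for DCS against WG, and with these tanks as a batch term 10 and 19. With only the tanks of the diets compared they were 0 by limma, with 2006 at an unadjusted p under 0.05, and 1. MIOX stood at 256 ± 69.3 in WG, 252 ± 77.9 in WS and 248 ± 79.8 in CG. Against WS, 2 genes passed, MIOX with a log2 change of -2.43 (SE 0.36, limma adjusted p = 0.0419) and 1 gene without a name, both given after their values were seen. Few genes passed between the other diets by limma, 2 for WS against WG, 2 for CS against CG, 2 for CG against WG, 2 for CS against WS and 4 for CS against WG, none with a vertebrate name. The same genes recurred, as seen after the calls. TRINITY_DN109037_c0_g1 and TRINITY_DN52306_c6_g1, above 0 in WG alone, were the calls of both WS and CG against WG. TRINITY_DN935_c6_g1 and TRINITY_DN44988_c0_g1 were those of CS against both CG and WS. Of the 4 for CS against WG, 3 were above 0 in 1 diet only. No gene passed between CG and WS by limma, and 1214 had an unadjusted p under 0.05, fewer than chance alone would give. The count was 7 for any diet without DCS replicate 2 or 4, and for DCS against WG it was 4 without WG replicate 4 and 9 without DCS replicate 1 or 4 or WG replicate 2. For DCS against CG it was 2 without CG replicate 3, 4 without CG replicate 1 or DCS replicate 4, 5 without CG replicate 4, 8 without DCS replicate 2 or WG replicate 4, 9 without DCS replicate 1 or CS replicate 3 and 10 without CG replicate 2. For DCS against WS it was 0 by limma without any single tank other than CS replicates 1 and 4, DCS replicates 1 to 3 and WG replicate 4, with 1349 to 2204 at an unadjusted p under 0.05 over the 21 alternatives with 0, these among them.

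Purified starch was compared with whole grain flour over both cereals. No gene passed by limma, and 1087 had an unadjusted p under 0.05, fewer than the 5% of 30844 genes that chance alone would give. The count was 1 without WG replicate 1 or 4, and 4 with moderation without trend or robust fitting. Among the smallest p, PDK2, a kinase that restrains pyruvate dehydrogenase, stood at 42.4 ± 4.01 in WG, 37.6 ± 3.28 in CG, 24.9 ± 5.58 in WS and 29.7 ± 5.34 in CS (n = 4 each), a log2 difference of -0.55 (SE 0.12, limma adjusted p = 0.718). AHNAK (AHNK), a large scaffold protein, stood at 3.64 ± 2.42 in WG, 8.8 ± 3.24 in WS, 6.58 ± 3.35 in CG and 17.1 ± 4.87 in CS, a log2 difference of 1.24 (SE 0.27, limma adjusted p = 0.718). An elongation factor 1-alpha gene (EF1A) was listed at 0 in all 4 CS tanks, at 0.693, 0, 0.983 and 0 in WS replicates 1 to 4, at 1.434, 2.587, 1.543 and 0.817 in WG and at 1.204, 1.406, 0.705 and 0.761 in CG (limma adjusted p = 0.718). Glycogen phosphorylase PYGL differed by 0.60 (SE 0.25, limma adjusted p = 1). The log2 differences were 0.09 for PKLR, 0.36 for G6PC1, -0.04 for PCK1, 0.56 for FASN and -0.19 for GYS2. They were 0.20 for SREBF1, 0.41 for CYP7A1 and 0.00 for IGF1.

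By camera, 3 marker lists of other cell types were called between starch and flour, and 0 members of any list passed, over all genes or adjusted over the list alone. Stromal and endothelial markers were higher with starch in 19 of 22 members (camera adjusted p = 0.00807, and adjusted p = 0.972 with an estimated correlation), with TAGLN at a log2 difference of 0.54. Pancreas markers were lower in 14 of 15 members (camera adjusted p = 0.0137, and adjusted p = 0.972 with an estimated correlation), with the trypsin entry PRSS at -1.09 (SE 1.34). The pancreas list level ranged over tanks from -3.258 to 3.233 and its difference of -0.859 between starch and flour did not pass an exact permutation test (p = 0.436, adjusted p = 0.744). Markers of bile duct, intestine, kidney and muscle were higher in 10 of 11 members (camera adjusted p = 0.0191, and adjusted p = 0.948 with an estimated correlation), with KRT8 at 0.31. Only 11 of the 27 symbols in that list were matched. Muscle CKM and PVALB and kidney UMOD were among those without a tested Trinity gene, so the list cannot be read as a rise of each of these tissues. The stromal call was lost without WS replicate 1, CG replicate 1, CS replicate 3 or WG replicate 3, with an adjusted p of up to 0.305, and the third call without WG replicate 3 (0.0583). The pancreas call was lost without WG replicate 1, CS replicate 1 or 4, CG replicate 1 or 4, or WS replicate 2 or 3 (up to 0.213), and it turned direction with the pancreas list level as a covariate (adjusted p = 0.899). That covariate is the mean of the same members, so it removes their difference by construction. Without tanks 36 and 43 the stromal (adjusted p = 0.328) and the third call (0.0691) were lost. By exact permutation tests of the list level, the difference was 0.197 for stromal markers (p = 0.252, adjusted p = 0.648) and 0.236 for the third list (p = 0.0185, adjusted p = 0.166).

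Corn was compared with wheat over both forms. No gene passed by limma, and 1287 had an unadjusted p under 0.05, fewer than the 5% of 30844 genes that chance alone would give. The count was 2 without CS replicate 1, and 3 with moderation without trend or robust fitting. Among the smallest p, IBP2A, an IGF-binding protein, stood at 4.07 ± 0.782 in WG and 4.54 ± 1.68 in WS against 1.4 ± 0.501 in CG and 2.65 ± 1.1 in CS (n = 4 each), a log2 difference of -0.85 (SE 0.18, limma adjusted p = 0.748). The acute phase protein SAA3 was listed at 0 in every wheat tank but WG replicate 4, where it was at 1.502, and stood at 0, 2.57, 3.926 and 1.426 in CG and at 1.378, 1.227, 3.261 and 4.664 in CS replicates 1 to 4 (limma adjusted p = 0.748). BT2A2, named by only 25.9% identity to a butyrophilin, was listed at 0 in every wheat tank but WS replicate 3, where it was at 0.29. It stood at 0, 2.166, 2.237 and 2.579 in CG and at 0, 3.742, 8.628 and 7.719 in CS (limma adjusted p = 0.748). The log2 differences were 0.09 for PKLR, -0.68 for G6PC1, -0.25 for PCK1, 0.16 for FASN and -0.43 for PYGL. They were 0.14 for GYS2, 0.14 for SREBF1, 1.1 for CYP7A1 and 0.03 for IGF1.

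Of the 6 lists camera called between corn and wheat, the proteasome was lower with corn in 32 of 33 members, with a median log2 difference of -0.31 (adjusted p = 5.87e-12, and adjusted p = 0.948 with an estimated correlation). PSMD7 differed by -0.51 and PSMD13 by -0.55. Leukocyte markers were higher in 18 of 21 members, with a median of 0.35 (camera adjusted p = 1.09e-08, and adjusted p = 0.948 with an estimated correlation), with lysozyme LYZ at 1.03 and the complement genes C1QA at 0.90 and C1QB at 0.87. The leukocyte list level differed by 0.385 (exact permutation p = 0.0143, adjusted p = 0.166). Acute phase and complement genes were higher in 28 of 31 members (camera adjusted p = 2.05e-06, and adjusted p = 0.948 with an estimated correlation), with haptoglobin HP at 0.66. The cytosolic ribosome (71 of 73 lower, adjusted p = 5.78e-06), oxidative phosphorylation (39 of 48 lower, adjusted p = 0.00562) and secreted hepatocyte proteins (16 of 19 higher, adjusted p = 0.0237) were also called, each with an adjusted p of 0.972 with an estimated correlation. No member passed, over all genes or adjusted over the list alone. The proteasome level was highest in WS tank 43 at 0.82 and WG tank 36 at 0.797, and without both the ribosome list turned to higher with corn (adjusted p = 0.0691). The ribosome call was lost without WG replicate 3 or WS replicate 4 alone, with an adjusted p of up to 0.206, and the oxidative phosphorylation call without CS replicate 4 or WS replicate 4, with an adjusted p of up to 0.137. The hepatocyte call was lost without CS replicate 1 or 2, WS replicate 2 or 4, WG replicate 3 or 4, or CG replicate 3 (up to 0.222). Without tanks 41 to 44 the ribosome (adjusted p = 0.0934), oxidative phosphorylation (0.291) and hepatocyte (0.16) calls were lost, the last also with these tanks as a batch term (0.0922). Without tanks 36 and 43 the oxidative phosphorylation (0.454) and hepatocyte (0.639) calls were lost, and with every Trinity gene of a name as a member the oxidative phosphorylation call was (0.089). By exact permutation tests of the list level, the difference was -0.33 for the proteasome (p = 0.0755, adjusted p = 0.967) and 0.275 for acute phase genes (p = 0.0789, adjusted p = 0.967). For oxidative phosphorylation, hepatocyte and ribosome genes that p was 0.16, 0.213 and 0.304.

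**Figure D3:**
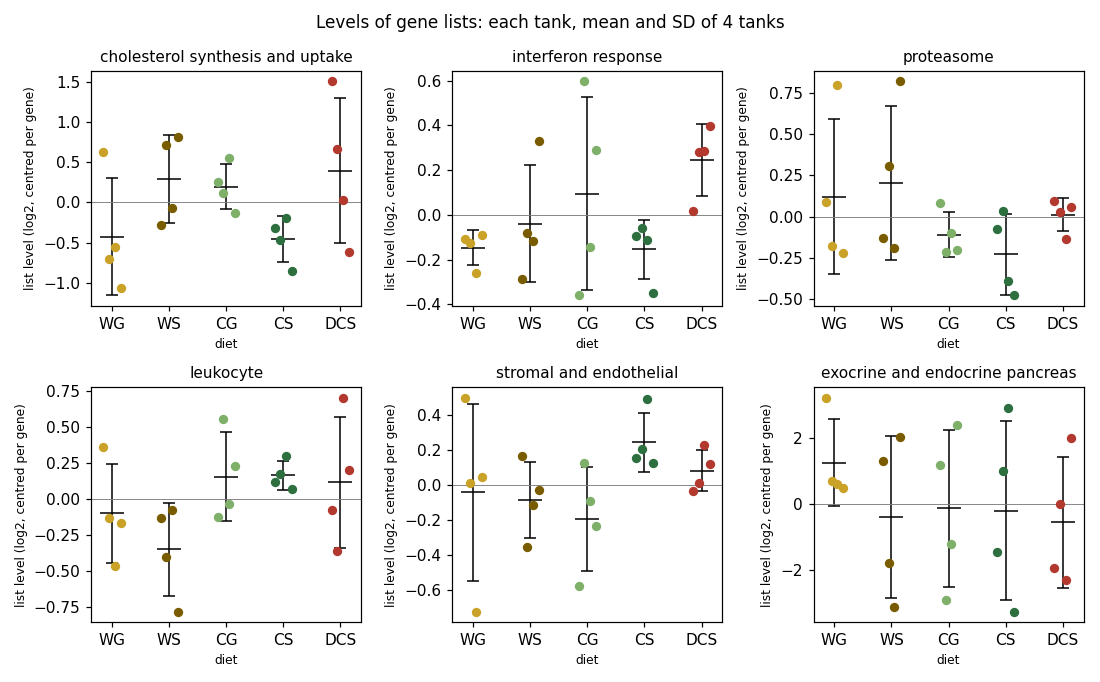
Level of 6 gene lists by diet, as the mean over members of log2(TMM-normalized TPM + 1) centred per gene. Points are single tanks, and bars are the mean and SD of 4 tanks. The pancreas list spans -3.258 to 3.233 over the tanks, and every diet overlaps the others.

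The interaction asks whether the difference between starch and flour itself differed between corn and wheat. No gene passed by limma, and 1592 had an unadjusted p under 0.05, close to the 5% of 30844 genes that chance alone would give. The count was 1 without DCS replicate 4, 2 without CS replicate 3, and 3 with moderation without trend or robust fitting. OACYL, an acyltransferase-like gene, stood at 7.19 ± 2.61 in WG, 18.5 ± 5.19 in WS, 15.7 ± 4.34 in CG and 7.51 ± 5.56 in CS (n = 4 each), with a log2 interaction of -2.40 (limma adjusted p = 0.32), and an apolipoprotein E gene (APOEB) had one of 2.20 (limma adjusted p = 0.291). The log2 interaction was -0.06 for PKLR, -0.11 for G6PC1, -0.17 for PCK1 and 0.42 for FASN. It was 0.26 for PYGL, -0.14 for GYS2, 0.41 for SREBF1, 1.36 for CYP7A1 and -0.33 for IGF1.

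As a group, 23 of 23 genes of cholesterol synthesis and uptake had a negative interaction, with a median of -1.40 (camera adjusted p = 1.92e-11, and adjusted p = 0.948 with an estimated correlation). The list level was -0.426 in WG and 0.292 in WS, but 0.196 in CG and -0.458 in CS. The log2 interaction was -2.67 for SQLE and -2.41 for HMGCS1, and no member passed, over all genes or adjusted over the list alone. Camera also called the stromal (17 of 22 positive, adjusted p = 0.000412), ribosome biogenesis (29 of 30 negative, adjusted p = 0.00145), acute phase (24 of 31 positive, adjusted p = 0.025), pancreas (14 of 15 positive, adjusted p = 0.036) and circadian clock (14 of 16 positive, adjusted p = 0.0387) lists. With an estimated correlation the adjusted p was 0.948 for the stromal and circadian lists and 0.972 for the other 3. The stromal call was lost without WG replicate 1 (adjusted p = 0.0769) and the ribosome biogenesis call without CS replicate 4 (0.179). The acute phase call was lost without WG replicate 1 or 2, CG replicate 1 or 4, WS replicate 2 or 4, or CS replicate 3 (up to 0.48), and the pancreas call without WG replicate 1 or 3, CS replicate 2 or 3, CG replicate 2 or 3, or WS replicate 2 or 3 (up to 0.517). The circadian call was lost without WG replicate 1 or 4, CS replicate 1 or 2, CG replicate 1 or 4, or WS replicate 2 or 4 (up to 0.145). Without tanks 41 to 44 the ribosome biogenesis (adjusted p = 0.743), acute phase (0.166) and circadian (0.325) calls were lost, without tanks 36 and 43 the acute phase (0.155) and circadian (0.0949) calls, and with the pancreas list level as a covariate the pancreas call (0.949). The last loss follows by construction, because the covariate is the mean of the pancreas members themselves.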

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

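The tests of tanks 41 to 44, of pancreas tissue and of identity to mammalian proteins, both sums over mammalian and mouse hits, and the test of genes seen in 1 diet were chosen only after the result was seen. The split counts given here and the test on genes under 90% identity were set beforehand.

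Single tanks stood far from the other 3 of their diet in 7 of 95 sets of 4 values, where chance gives about 1 in 20, or 4.75. SC6A8 was at 1.29 in CG replicate 4 against 0.115 to 0.269. G6PC1 was at 465 in WG replicate 3 against 232 to 267, and at 594 in WS replicate 1 against 322 to 337. BHMT was at 4230 in CS replicate 2 against 6950 to 7500. PCK1 was at 793 in WS replicate 4 against 15.6 to 33.6, and FASN at 29.5 in DCS replicate 1 against 4.66 to 7.36. The pancreas list level was 3.23 in WG replicate 1 against 0.485 to 0.7.

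The difference between starch and flour differed between corn and wheat in 6 lists by camera: cholesterol synthesis and uptake (adjusted p = 1.92e-11), stromal (0.000412), ribosome biogenesis (0.00145), acute phase (0.025), pancreas (0.036) and circadian clock (0.0387). None was called with an estimated correlation, where the smallest adjusted p was 0.948.

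Between DCS and CS, 11 genes passed, and 1 of 35 splits of the 8 tanks gave as many, the real one, with at most 6 in any other. That is the smallest share 35 splits allow and argues against chance, but it was not adjusted over the contrasts tested this way. Tanks 41 to 44 hold 1 DCS and 1 CS tank, so a shift common to them cancels in this contrast, and leaving them out cannot test it. Without them the log2 changes were at a median of 0.983 of their size, from 0.769 to 1.04, so these tanks alone did not carry the changes. Only 3 of the 11 still passed with fewer tanks. The tables argue against pancreas tissue as the cause, because 10 of the 11 still passed with the pancreas list level as a covariate. Against transcripts identical to mammalian proteins, 0 of the 11 had such a best hit, which speaks only for the 6 that have a name. After Trinity genes of 1 name were summed, which leaves genes without a name as they are, 8 of the 11 still passed, with log2 changes of -3.06 for MIOX, 2.40 for GPDM and 1.99 for SLC25A12, so that how reads were shared stays open for G0S2 at 0.93 and SC6A8 at 1.46, which no longer passed, and for genes without a name, as does any handling that went with diet. The diet may be the source of the change in MIOX, as a hypothesis found and tested on the same tanks.

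Tanks 41 to 44 had 93343 to 100949 Trinity genes above 0, against 67923 to 83315 in the others. More reads would leave summed TPM unmoved, and the sum over genes with a mammalian best hit at 99% identity or more lay partly within the range of the other tanks, the lowest of the 4 at 0.785 of the highest of the other 16. The sum over mouse best hits alone lay above it, at 1.69. On average both sums were higher in these tanks, at 1.32 times the mean of the others for mammalian and 1.93 times for mouse hits. The highest of the other 16 in the mammalian sum was WG tank 36 at 70260. All 4 mouse sums, 10972 to 11440, lay above the others at 4919 to 6488, which argues against more reads alone for those genes. That narrower class is the one in which the excess was first noticed, and it was tested after the broader value was known. Whether these tanks also had more reads stays open. By number above 0 both classes were higher, 16864 to 17731 against 8587 to 11282 for mammalian and 9263 to 9846 against 3222 to 5635 for mouse hits. Genes without a hit were higher too, 48951 to 54393 against 34963 to 47891. Such numbers depend on depth, which is unknown, so they do not settle it. Reads from another organism alone cannot be told apart, because genes under 90% identity were above 0 in 19304 to 19934 against 17867 to 19240, a ratio of 1.003 of lowest to highest, and no biological explanation was tested.

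Some genes were above 0 in all 4 tanks of 1 diet and in no other tank. Among them were 2 of the 11 genes between DCS and CS, TRINITY_DN44988_c0_g1 in CS and TRINITY_DN55774_c0_g1 in DCS. Of 2716 genes above 0 in exactly 4 tanks, 4 had this pattern and 2.8 would by chance (permutation p = 0.299), so chance presence may account for it. In tanks 41 to 44, 24 such genes were found, against 10 for the next most common set of 4 tanks.

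Few splits of the same tanks gave as many genes for DCS against CG (1 of 35 as large, 17 genes, at most 5 elsewhere), DCS against WG (1 of 35, 15, at most 7), and any diet (3 of 100, 12, up to 27). The real split is always counted, so 1 of 35 is the smallest share possible. These shares argue against chance, but they were not adjusted over the contrasts tested this way, so chance is not excluded. The counts for DCS against CG and WG were 1 and 4 without tanks 41 to 44, 10 and 19 with a batch term for them, and, with only the tanks of the diets compared, 0 by limma (2006 at an unadjusted p under 0.05) and 1. The splits give no argument against chance for WS against WG (10 of 35, 2 genes, up to 19), CS against CG (11, 2, up to 4), CG against WG (4, 2, up to 3), CS against WS (12, 2, up to 5), DCS against WS (12, 2, up to 4), CS against WG (5, 4, up to 5) or CG against WS (35, 0 by limma with 1214 at an unadjusted p under 0.05, up to 4). For starch against flour, corn against wheat and the interaction, all 100 splits gave at least the 0 found by limma, with 1087, 1287 and 1592 at an unadjusted p under 0.05, and up to 3, 4 and 47 genes. Splits with 19, 27 or 47 genes point to a structure of the samples, and what it is was not tested. For the called lists, chance is not excluded for starch against flour (96 of 100, 3 lists, up to 14), corn against wheat (64 of 100, 6, up to 15), the interaction (66 of 100, 6, up to 16) or DCS against CS (17 of 35, 6, up to 15). Camera at the preset correlation called at least 1 list in each of the 99 other splits, and in each of the 34 for DCS against CS.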

How the results depend on the processing

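The fits with tanks 41 to 44 as a batch term or left out, without WG tank 36 and WS tank 43, with the pancreas level, without genes identical to mammalian proteins and with values above 0 in 10 tanks were chosen only after the data were seen. No paired analysis was possible because no tank number is shared between diets. Over 124 single genes and lists, 4280 alternatives gave 3885 with the same direction and side of the threshold, 314 no longer past it, 2 newly past it and 79 reversed. Most of the 124 did not pass in the main fit, and for them the same side means staying short of the threshold. The 314 losses all fall on the results that did pass, so the pooled count says little of how stable those are. MIOX between DCS and CS was lost only with the DCS and CS tanks fitted alone (adjusted p = 0.131), and its log2 change lay between -3.40 and -2.68. Depth is unknown, and the cause of each change below was not tested, except that fewer genes or tanks are tested by construction in the stricter filters and smaller fits.

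With a pseudocount of 0.1, the count of genes was 5 for DCS against CS, 9 for DCS against CG, 6 for DCS against WG and 10 for DCS against the other 4 diets. With a pseudocount of 5, the count of genes was 1 for starch against flour, 4 for DCS against WS and 29 for DCS against the other 4 diets. With no filter on low values, the count of genes was 23 for any diet, 8 for CS against CG, 4 for CG against WG, 6 for CS against WS, 4 for DCS against WG, 1 for DCS against WS and 7 for CS against WG. With a minimum of 5 in 4 tanks, by which fewer genes were tested, the count of genes was 4 for any diet, 5 for DCS against CS, 0 for WS against WG, 0 for CS against CG, 0 for CG against WG, 0 for CS against WS, 4 for DCS against CG, 6 for DCS against WG, 1 for DCS against WS, 0 for CS against WG and 8 for DCS against the other 4 diets. After median-ratio rescaling, the count of genes was 11 for DCS against CG and 0 for DCS against WS. The sign turned for log2 differences of 0.07 for PKLR and 0.03 for G6PC1 in the interaction. After quantile normalization, the count of genes was 1 for starch against flour, 10 for DCS against CG and 0 for DCS against WS. Turned in sign were log2 differences of 0.01 for PCK1 and 0.02 for IGF1 in starch against flour, and -0.01 for IGF1 in corn against wheat. With moderation without trend or robust fitting, the count of genes was 4 for starch against flour, 3 for corn against wheat, 3 for the interaction, 1 for CS against WS and 4 for DCS against WS. With tank number as a covariate, the count of genes was 1 for starch against flour and 0 for DCS against WS. Log2 differences that turned sign were 0.06 for PCK1 in the interaction. With Trinity genes summed per protein entry, the count of genes was 1 for DCS against WS. The sign turned for log2 differences of -0.03 for FASN in corn against wheat, and -0.18 for TXTPB in DCS against the other 4 diets. With isoforms in place of genes, the count of genes was 2 for starch against flour, 6 for DCS against CS, 1 for WS against WG, 5 for DCS against CG, 7 for DCS against WG and 1 for CG against WS. With tanks 41 to 44 as a batch term, the count of genes was 1 for starch against flour, 10 for DCS against CG and 0 for DCS against WS, and the count of called lists was 11 for the interaction. Turned in sign were log2 differences of 0.01 for IGF1 in starch against flour, and 0.01 for PKLR in the interaction. Without tanks 41 to 44, the count of genes was 1 for starch against flour, 1 for the interaction, 4 for DCS against CS, 4 for WS against WG, 5 for CG against WG, 1 for DCS against CG, 4 for DCS against WG, 0 for DCS against WS, 8 for CS against WG and 5 for DCS against the other 4 diets, and the count of called lists was 5 for starch against flour. Log2 differences that turned sign were 0.04 for IGF1 in starch against flour, and -0.01 for PKLR, 0.64 for PCK1, -0.03 for FASN and -0.06 for SREBF1 in corn against wheat, and 0.06 for G6PC1, 0.52 for PCK1 and 0.31 for GYS2 in the interaction. Without WG tank 36 and WS tank 43, the count of genes was 0 for WS against WG, 1 for CS against WS, 7 for DCS against WG and 1 for DCS against WS, and the count of called lists was 3 for corn against wheat. There the cytosolic ribosome list turned direction for corn against wheat (adjusted p = 0.0691). The sign turned for log2 differences of -0.10 for PKLR, 0.60 for PCK1, -0.09 for FASN and -0.14 for SREBF1 in corn against wheat, and 0.68 for PCK1 and 0.01 for GYS2 in the interaction. With the pancreas list level as a covariate, the count of genes was 1 for CS against WS. There the exocrine and endocrine pancreas list turned direction for starch against flour (adjusted p = 0.899). The covariate is the mean of that list's own members, so the change of the list and of its member PRSS follows by construction. Turned in sign were log2 differences of 0.04 for PCK1, 0.03 for IGF1 and 0.04 for PRSS in starch against flour, and 0.01 for G6PC1 in the interaction. Among genes above 0 in at least 10 tanks, the count of genes was 0 for WS against WG, 1 for CS against CG, 0 for CG against WG, 0 for CS against WS, 0 for DCS against WS and 1 for CS against WG, and the count of called lists was 5 for starch against flour. With only the tanks of the diets compared, the count of genes was 1 for the interaction, 0 for DCS against CS, 0 for WS against WG, 1 for CS against CG, 0 for CG against WG, 0 for CS against WS, 0 for DCS against CG, 1 for DCS against WG, 0 for DCS against WS, 1 for CG against WS and 1 for CS against WG. With an estimated correlation, the count of called lists was 0 in each of the 4 contrasts. With fry, the count of called lists was 0 in each of the 4 contrasts. With every Trinity gene of a name as a list member, the count of called lists was 12 for the interaction.

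Each tank was left out in turn, with these ranges. For any diet the count of genes was 7 to 16 against 12 with all tanks, 7 without DCS replicate 2 or DCS replicate 4. For starch against flour the count of genes was 0 to 1 against 0 with all tanks, 1 without WG replicate 1 or WG replicate 4. For corn against wheat the count of genes was 0 to 2 against 0 with all tanks, 2 without CS replicate 1. For the interaction the count of genes was 0 to 2 against 0 with all tanks, 1 without DCS replicate 4, 2 without CS replicate 3. For DCS against CS the count of genes was 3 to 15 against 11 with all tanks, 3 without CS replicate 3 or CS replicate 4, 5 without DCS replicate 4, 6 without CS replicate 2. For CS against WS the count of genes was 1 to 6 against 2 with all tanks, 1 without any single tank other than CS replicate 1, WS replicate 1, WG replicate 2, WG replicate 3, WG replicate 4 and CS replicate 4, 4 without CS replicate 1 or WG replicate 4, 6 without WS replicate 1. For DCS against CG the count of genes was 2 to 19 against 17 with all tanks, 2 without CG replicate 3, 4 without CG replicate 1 or DCS replicate 4, 5 without CG replicate 4, 8 without DCS replicate 2 or WG replicate 4, 9 without DCS replicate 1 or CS replicate 3, 10 without CG replicate 2. For DCS against WG the count of genes was 4 to 17 against 15 with all tanks, 4 without WG replicate 4, 9 without DCS replicate 1, WG replicate 2 or DCS replicate 4. For DCS against WS the count of genes was 0 to 8 against 2 with all tanks, 0 without any single tank other than CS replicate 1, DCS replicate 1, DCS replicate 2, DCS replicate 3, WG replicate 4 and CS replicate 4, 1 without DCS replicate 2, 4 without CS replicate 4, 8 without DCS replicate 3. Called lists for starch against flour numbered 2 to 6 against 3 with all tanks, 5 without WG replicate 1, CS replicate 2, WS replicate 3, DCS replicate 3, WG replicate 4 or WS replicate 4, 6 without WG replicate 3. Called lists for corn against wheat numbered 3 to 10 against 6 with all tanks, 3 without WS replicate 4, 10 without CG replicate 1 or WS replicate 3. Called lists for the interaction numbered 3 to 12 against 6 with all tanks, 3 without WG replicate 1, 10 without WS replicate 3, 11 without WG replicate 4, 12 without WS replicate 1. In starch against flour the log2 difference by gene was, for PCK1 -0.68 without WS replicate 4 to 0.25 without WS replicate 1, CYP7A1 -0.01 without WG replicate 3 to 0.82 without WG replicate 1, IGF1 -0.10 without CS replicate 2 to 0.09 without CS replicate 4. In corn against wheat the log2 difference by gene was, for PKLR -0.03 without WS replicate 4 to 0.17 without WS replicate 1, PCK1 -0.54 without WS replicate 1 to 0.39 without WS replicate 4, FASN -0.03 without CS replicate 1 to 0.35 without WG replicate 1, GYS2 0.00 without CG replicate 1 to 0.28 without WS replicate 4, SREBF1 -0.03 without WS replicate 4 to 0.26 without WG replicate 1, IGF1 -0.06 without CS replicate 2 to 0.12 without CG replicate 2. In the interaction the log2 difference by gene was, for PKLR -0.30 without WS replicate 4 to 0.10 without WS replicate 1, G6PC1 -0.61 without CG replicate 4 to 0.18 without CG replicate 2, PCK1 -0.76 without WS replicate 1 to 1.1 without WS replicate 4, PYGL -0.06 without CG replicate 3 to 0.53 without CG replicate 2, GYS2 -0.37 without CG replicate 3 to 0.15 without CG replicate 1. In DCS against CS the log2 difference by gene was, for FASN -0.05 without DCS replicate 1 to 0.88 without CS replicate 1.

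Over the fit with all tanks and the alternatives in which limma gave a count of 0, those that leave out single tanks included, the genes at an unadjusted p under 0.05 numbered at most 7058 for starch against flour, 380 to 7289 for corn against wheat, 464 to 8112 for the interaction, 343 to 8620 for CG against WS, 293 to 1253 for WS against WG, 421 for CS against CG, 203 to 1074 for CG against WG, 717 to 1635 for CS against WS, 240 for CS against WG, 1349 to 2204 for DCS against WS, 1766 for DCS against CS and 2006 for DCS against CG. Chance alone would give about 5% of the genes tested. The counts of 7058, 7289, 8112 and 8620 came with no filter on low values, where more genes were tested.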

Other observations

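The contrast of DCS with the mean of the other 4 diets, its test and its count of splits were chosen only after the pairwise results were seen.

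In DCS against the other 4 diets 19 genes passed, 18 higher and 1 lower, and 1 of 100 splits gave as many, with at most 7 in any other. Of the 19, only 3 still passed without tanks 41 to 44 and 9 with a pseudocount of 0.1. With a minimum of 5 in 4 tanks, 7 of the 19 were still tested and 6 passed. Beyond the genes between DCS and CS, those with a name were ELOV6, a fatty acid elongase, at a log2 change of 1.66 (limma adjusted p = 0.0041), SO1C1, an organic anion transporter, at 2.05 (0.00353), DESI2 at 1.21 (0.00353), CSDC2 at 1.26 (0.0413), TXTPB, a mitochondrial tricarboxylate carrier, at 1.1 (0.0413) and GPAM at 0.95 (0.0477). All 6 were lost without tanks 41 to 44, and the largest adjusted p over the alternatives was 0.909 for ELOV6, 0.974 for SO1C1, 0.11 for DESI2, 0.145 for CSDC2, 0.946 for TXTPB and 0.348 for GPAM. When Trinity genes of 1 name were summed, the log2 change was 0.16 for SO1C1, 0.68 for ELOV6, -0.18 for TXTPB, 1.03 for DESI2 and 0.94 for GPAM, none of which passed, and 1.23 for CSDC2, which did. Leaving out single tanks ended the call of GPAM in all but CG replicates 2 and 3 and WS replicate 2, that of TXTPB in all but DCS replicates 1 and 2, WS replicates 1 and 4 and CG replicate 2, and that of CSDC2 in all but WG replicate 1, WS replicates 1 and 4 and CG replicate 2. Of 19 genes of fatty acid and triglyceride synthesis 14 were higher in DCS than in CS, and the list was not called (camera adjusted p = 0.269). Of 25 glycolysis genes 13 were higher, with a median log2 difference of 0.01 (camera adjusted p = 0.569).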
